A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

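RNA from 2 strains of Saccharomyces cerevisiae was compared on 9 two-colour spotted arrays of open reading frames. JCW27-TOPA lacks topoisomerase I (Δtop1), and JCW28-TOPA lacks it and carries the heat-sensitive topoisomerase II allele top2-4. Both strains hold a plasmid named TOPA and were grown in synthetic medium without leucine. Per the labels, cultures grew at 26C into log phase and were moved to 35C, which inactivates the top2-4 product. A folder name in the file headers gives a slightly higher temperature. Samples were taken at 0, 30 and 120 min, with 3 arrays per time from independently grown cultures, which every test treats as independent replicates. Deviations from the time means correlated between 0 and 120 min arrays (r = -0.508 to 0.490 across genes), which the model leaves out. JCW27 was labelled with Cy5 and JCW28 with Cy3 on all 9 arrays. With no dye swap, a gene-specific dye effect is part of each strain ratio, whereas it cancels in a change between times.

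The deposited scanner tables, written by GenePix Pro 5.0.1.33 on a GenePix 4000B per the file headers, give each spot's median pixel intensity and that of its local background at 635 nm (Cy5) and 532 nm (Cy3). The deposited columns also give the SD of the background as an intensity. The percent of saturated pixels and the score by which spots were marked as usable were computed by that software per the file headers, with no normalization or background correction. Each array carried 13824 spots, among them 280 blank spots and 352 negative control spots of random sequence. Most of the 6388 gene identifiers were printed on 2 spots. The authors also deposited a value table, which holds log2 ratios of Cy3 over Cy5 per spot, normalized within each array by a method that is not stated. Its direction was settled against the scanner values of the same spots (correlations 0.967 to 0.983 per array). This table holds 8802 to 11103 values per array, with column medians from -0.048 to 0.038, and served as an alternative.

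The number of arrays limits the precision. Spots marked as bad or absent by the scanner software, 0 to 2045 per array, were left out. The median intensity above local background was 208 to 353 in Cy5 and 241.5 to 371 in Cy3. A gene counted as above background where the foreground exceeded the local background by more than 2 background SD. By that measure 83.5% to 95.3% of the genes on an array were above background in JCW27 and 84.6% to 95.0% in JCW28.

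Scanner intensities were background-corrected with normexp (offset 50), and log2 ratios of JCW28 over JCW27 were normalized by loess within each array with limma 3.58.1 in R 4.3.3, control spots having no weight. Loess places the typical gene of each array at a log2 ratio near 0. A change therefore stands for a difference from the typical gene, and a shift of all transcripts alike cannot be seen. Spots of one identifier were averaged, and a gene entered the tests when measured on at least 2 of the 3 arrays of every time. This left 5927 genes, of which 5532 had a chromosome position and 5422 were measured on all 9 arrays. One limma model with a mean per time was fitted to all 9 arrays, so the 3 times share one estimate of the spread. Strain differences at each time, changes between times and an F test over both changes from 0 min were tested two-sided with moderated statistics (eBayes). The Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05, and errors are the model's standard errors (SE).

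Lists of genes for 32 processes, complexes and gene families were fixed before the data were examined, together with the comparisons and the alternatives, except for those named below as chosen later. They cover topoisomerases, ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, heat shock proteins, the environmental stress response, glycolysis, respiration, gluconeogenesis, histones, G1/S, G2/M and M/G1 cell cycle genes, DNA damage, phosphate, galactose, Gcn4 targets of amino acid biosynthesis, methionine and sulfur, sterols, iron and copper, the cell wall, the proteasome, RNA polymerase II, chromatin, 4 subtelomeric families (seripauperins, COS, YRF1 helicases and a mixed group of sugar, vitamin and flocculation genes), mating and MATa genes, MATalpha genes, meiosis, and quiescent cells. Each list with at least 5 genes on all 9 arrays was tested with camera at a preset correlation of 0.01, adjusted over the 31 tested lists within a comparison. Camera with an estimated correlation and fry stood beside it. A gene on several lists counts in each, and list counts are given over all genes tested and adjusted over the list alone. A call by camera at the preset correlation is what "passed" means for a list.

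Genes were named by a fixed rule. For the change from 0 to 120 min it takes up to 10 of the largest rises and of the largest falls among genes past the threshold whose 3 values at one time all lie above those at the other. For every other comparison it takes the 5 largest in each direction under the same condition, with all 3 arrays on one side of 0 for a strain difference. Each list that passed in a change over time adds up to 4 members with the smallest p in its direction. TOP1, TOP2, TOP3, LEU2, URA3, TRP1, HIS3 and mating-type genes are always given as checks of the labels. Probes of near-identical copies, such as RPL4A and RPL4B, HXT6 and HXT7, and members of the seripauperin, COS and YRF1 families, can hybridise to each other's transcripts, so values of such copies are values of the family.

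The positional question was whether the strain ratio depends on the distance to a chromosome end. The files name no genome build and hold no chromosome lengths, so no coordinates are given, and the planned distance of 100 kb was replaced by 50 protein-coding genes counted from the nearer end in the gene table (R64 systematic names). Distances of 50 and 150 kb became 25 and 75 genes, and removal of the outer 20 kb became removal of the 10 outermost genes. For each comparison the median of the near genes minus that of the interior genes was computed. It was tested across the 15 chromosomes with interior genes by an exact two-sided sign-flip test, across genes by 10000 circular permutations (rotations) of the gene order within chromosomes, and across the 3 arrays per time by an exact two-sided permutation test, whose smallest possible p is 0.1. Coding length, mean intensity and the orientation of neighbouring genes were described across genes with 2000 rotations, in a family of 15 relations.

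The alternatives were: no background subtraction or plain subtraction; median centring, no normalization, print-tip loess or scaling between arrays; the deposited table; a filter that keeps genes above background on at least 5 arrays; marked spots kept; genes on all 9 arrays alone; arrays of the compared times alone; a trended and robust spread; the replicate number as a block; and each array left out in turn. Scan day follows time exactly, so no block for it could be fitted. The tests were tried on simulated changes from 0 to 120 min. They recovered 60% of genes planted at a log2 size of 0.5, 90% at 1, 94% at 2 and 100% at 3, and called 11 unchanged genes. A shift of 0.4 planted near the ends was measured as 0.391, and none as 0.0011. Without one the sign-flip p passed in 3 of 40 simulations. These rates need not hold where genes or arrays correlate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.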

Results

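The series compared transcript levels in 2 yeast strains at 3 times after a shift from 26C to 35C. JCW28 carries the heat-sensitive top2-4 allele and JCW27 has normal topoisomerase II. Both lack topoisomerase I and carry the TOPA plasmid, and the series title names the accumulation of positive supercoils in DNA. Every array gave the ratio of JCW28 to JCW27 in one pair of cultures (strain ratio, 3 arrays per time). Rises and falls are of this ratio, and which strain moved was not tested. Of 5927 genes tested, 3856 changed in strain ratio over the 3 times by the F test. Medians of lists are on the log2 scale, their adjusted p comes from camera, and ranges of medians are over the scaling and background settings.

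Before the shift, JCW28 had higher transcript levels of ribosome biogenesis genes and lower levels of stress genes than JCW27, which addresses how the strains differ at the permissive temperature (n = 3 arrays). HSP42, a small heat shock protein gene, HXK1, which encodes a hexokinase, and TSL1, which encodes a subunit of the trehalose synthase complex, were lower in JCW28 by 2.62-fold, 2.51-fold and 2.35-fold. FCF1 (YDR339C) and UTP4 (YDR324C), both with roles in ribosomal RNA processing, were higher by 2.76-fold and 2.57-fold. The log2 ratio of FCF1 was 1.46 (SE 0.088, adjusted p = 4.09e-06), and that of HSP42 (YDR171W) was -1.39 (SE 0.081, adjusted p = 4.09e-06). The other largest differences were SVF1 (YDR346C) at 1.42 (SE 0.063), BCP1 (YDR361C) at 1.38 (SE 0.083) and YDR341C, an arginyl-tRNA synthetase gene, at 1.28 (SE 0.069). In the other direction stood YER053C-A at -1.38 (SE 0.11), HXK1 (YFR053C) at -1.33 (SE 0.079), BTN2 (YGR142W) at -1.23 (SE 0.16) and TSL1 (YML100W) at -1.23 (SE 0.091). Each of these genes had all 3 arrays on one side of 0. The 5 genes with the largest higher values, FCF1, SVF1, BCP1, UTP4 and YDR341C, all lie in one run of neighbouring genes on chromosome IV that was higher in JCW28 at all 3 times, described in the closing section.

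Among the lists at 0 min, ribosome biogenesis genes had 104 higher, 0 lower and 10 not passing of 114 (105 and 0 adjusted over the list alone), with median 0.54, adjusted p = 6.84e-29. The call was lost at adjusted p = 0.0892 with an estimated correlation. Stress response genes under Msn2 and Msn4, which switch on with many kinds of stress, had 0 higher, 54 lower and 11 not passing of 65 (0 and 55 adjusted over the list alone), with median -0.61, adjusted p = 7.28e-24 and adjusted p = 0.0489 with an estimated correlation, so that this call held. For heat shock proteins and chaperones the counts were 0 higher, 21 lower and 10 not passing of 31 (0 and 21 adjusted over the list alone), with median -0.47, adjusted p = 1.26e-09, and adjusted p = 0.115 with an estimated correlation. Gcn4 targets, which build amino acids, had 34 higher, 2 lower and 13 not passing of 49 (35 and 2 adjusted over the list alone), with median 0.35, adjusted p = 3.19e-09, and adjusted p = 0.0989 with an estimated correlation. Genes of respiration and the TCA cycle had 4 higher, 26 lower and 17 not passing of 47 (4 and 26 adjusted over the list alone). The list median was -0.28 (adjusted p = 0.000535, and adjusted p = 0.555 with an estimated correlation). Subunits of RNA polymerases I and III, which make ribosomal and transfer RNA, had 16 higher, 1 lower and 19 not passing of 36 (18 and 1 adjusted over the list alone), with median 0.21, adjusted p = 0.00913, and adjusted p = 0.0989 with an estimated correlation.

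Smaller lists also differed at 0 min. Gluconeogenesis and fatty acid oxidation genes had 2 higher, 9 lower and 11 not passing of 22 (2 and 9 adjusted over the list alone), with median -0.18, adjusted p = 0.0129, and adjusted p = 0.361 with an estimated correlation. Genes of quiescent cells, of which 11 of 19 are on other lists as well, had 1 higher, 9 lower and 7 not passing of 17 (1 and 10 adjusted over the list alone). These genes had a median of -0.51 (adjusted p = 0.000683, and adjusted p = 0.24 with an estimated correlation). Galactose genes had 1 higher, 5 lower and 4 not passing of 10 (3 and 6 adjusted over the list alone), with median -0.29, adjusted p = 0.00736, and adjusted p = 0.11 with an estimated correlation. YRF1 helicase genes, which lie at chromosome ends, had 5 higher, 0 lower and 3 not passing of 8 (5 and 0 adjusted over the list alone), with median 0.32, adjusted p = 0.0389, and adjusted p = 0.574 with an estimated correlation. The YRF1 call ended without 0 min replicate 1 (adjusted p = 0.0767) and the galactose call without 30 min replicate 2 (adjusted p = 0.0596). The latter used another gene set (median -0.29) than the 7 genes on all 9 arrays (-0.48). The YRF1 call also ended with median centring (0.434) and in the authors' table (0.329), and the gluconeogenesis call in that table (0.105). The medians ranged from -0.43 to -0.11 for gluconeogenesis, -0.82 to -0.21 for galactose genes, 0.14 to 0.43 for YRF1 genes and 0.19 to 0.45 for Gcn4 targets. In all, 2409 genes passed at 0 min, 1231 higher and 1178 lower, and 47 of them differed by more than 2-fold. The count fell to 1363 without 0 min replicate 3 and to 1510 without 0 min replicate 2, while 0 min replicate 1 correlated less with the other two arrays (r = 0.571 and 0.626 across genes) than they did with each other (r = 0.916).

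After 30 min at 35C, ribosomal protein genes were lower and stress and respiration genes higher in JCW28 than in JCW27 (n = 3 arrays). HXT6 (YDR343C), a high-affinity glucose transporter gene in the chromosome IV run, was higher by 4.76-fold at a log2 ratio of 2.25 (SE 0.068, adjusted p = 4.81e-08). SPG1 (YGR236C), a gene of stationary-phase cells, was higher by 3.69-fold at 1.88 (SE 0.083, adjusted p = 4.27e-07). RNR1 (YER070W), the large subunit of ribonucleotide reductase, was lower by 3.24-fold at -1.70 (SE 0.075, adjusted p = 4.27e-07), and PHO3 (YBR092C), an acid phosphatase gene, by 3.02-fold at -1.59 (SE 0.083, adjusted p = 1e-06). The other largest lower values were TDA6 (YPR157W) at -1.79 (SE 0.085), ATG41 (YPL250C), an autophagy gene, at -1.69 (SE 0.089), and YDL038C at -1.56 (SE 0.099). YDR250C, YLR311C and YOR053W also ranked among the largest, at 2.04 (SE 0.58), 1.98 (SE 0.46) and 1.87 (SE 0.56), but rested on 30 min replicate 2. Without that array their log2 ratios were 0.72, 0.98 and 0.63, all still past the threshold. YDR250C and YOR053W were not above background in JCW27 on any 30 min array. Against that background the mean of the 3 arrays was at least 3.86-fold and at least 3.54-fold higher in JCW28. These bounds hold for that mean only, since it rested on 30 min replicate 2.

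Growth-related lists were lower in JCW28 at 30 min. Ribosomal protein genes had 0 higher, 123 lower and 8 not passing of 131 (0 and 124 adjusted over the list alone). The median of the list was -0.51 (adjusted p = 2.34e-23, and adjusted p = 0.165 with an estimated correlation). Ribosome biogenesis genes had 3 higher, 92 lower and 19 not passing of 114 (5 and 93 adjusted over the list alone), with median -0.49, adjusted p = 6.44e-15, and adjusted p = 0.116 with an estimated correlation. The RNA polymerase I and III subunits had 3 higher, 20 lower and 13 not passing of 36 (3 and 20 adjusted over the list alone), with median -0.28, adjusted p = 0.000438, and adjusted p = 0.0759 with an estimated correlation. Gcn4 targets had 1 higher, 30 lower and 18 not passing of 49 (1 and 32 adjusted over the list alone). Their median was -0.28 (adjusted p = 9.08e-07, and adjusted p = 0.116 with an estimated correlation). G1/S genes, which rise before DNA replication, had 0 higher, 30 lower and 11 not passing of 41 (0 and 31 adjusted over the list alone), with median -0.35, adjusted p = 1.83e-07, and adjusted p = 0.116 with an estimated correlation. Histone genes had 0 higher, 7 lower and 4 not passing of 11 (0 and 7 adjusted over the list alone), with median -0.24, adjusted p = 0.0123, and adjusted p = 0.247 with an estimated correlation.

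Higher in JCW28 at 30 min were the stress response genes, with 58 higher, 2 lower and 5 not passing of 65 (58 and 2 adjusted over the list alone), median 0.64, adjusted p = 9.85e-16, and adjusted p = 0.0759 with an estimated correlation. Respiration genes had 36 higher, 1 lower and 10 not passing of 47 (37 and 1 adjusted over the list alone). The list median was 0.45 (adjusted p = 4.71e-09, and adjusted p = 0.184 with an estimated correlation). Gluconeogenesis genes had 17 higher, 0 lower and 5 not passing of 22 (18 and 0 adjusted over the list alone), with median 0.40, adjusted p = 1.28e-05, and adjusted p = 0.116 with an estimated correlation. Genes of quiescent cells had 13 higher, 0 lower and 4 not passing of 17 (14 and 0 adjusted over the list alone), with median 0.81, adjusted p = 3.51e-07, and adjusted p = 0.116 with an estimated correlation. Proteasome genes, whose products degrade proteins, had 22 higher, 0 lower and 12 not passing of 34 (22 and 0 adjusted over the list alone). These genes had a median of 0.26 (adjusted p = 1.49e-05, and adjusted p = 0.116 with an estimated correlation). Glycolysis genes had 16 higher, 1 lower and 6 not passing of 23 (16 and 1 adjusted over the list alone), with median 0.39, adjusted p = 1.34e-05, and adjusted p = 0.21 with an estimated correlation, but their median was negative with median centring, with no normalization and in the authors' table.

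Families at chromosome ends were among the lists that passed at 30 min. COS genes had 10 higher, 0 lower and 1 not passing of 11 (10 and 0 adjusted over the list alone), with median 0.40, adjusted p = 0.00138, and adjusted p = 0.182 with an estimated correlation. YRF1 genes had 8 higher, 0 lower and 0 not passing of 8 (8 and 0 adjusted over the list alone), with median 0.55, adjusted p = 0.000257, and adjusted p = 0.213 with an estimated correlation. The mixed sugar, vitamin and flocculation families had 24 higher, 6 lower and 19 not passing of 49 (24 and 7 adjusted over the list alone). The median of the list was 0.20 (adjusted p = 0.0407, and adjusted p = 0.636 with an estimated correlation). That last call ended without 30 min replicate 1 (adjusted p = 0.0696) or replicate 3 (0.0916), with the replicate number as a block (0.0501) and in the authors' table (0.339), as did the gluconeogenesis call in that table (0.0832). The 30 min medians ranged from -1 to -0.47 for ribosomal protein genes, -0.53 to -0.25 for Gcn4 targets, -0.51 to -0.18 for histone genes. They ranged from 0.39 to 0.66 for stress genes, 0.25 to 0.78 for gluconeogenesis, 0.25 to 0.56 for YRF1 genes and 0.17 to 0.40 for the mixed families. In all, 3323 genes passed at 30 min, 1681 higher and 1642 lower. By more than 2-fold, 150 were higher and 45 lower. The array that stood apart was 30 min replicate 2 (r = 0.731 and 0.717 across genes with the others, which had r = 0.901).

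At 120 min the highest strain ratios were at genes near chromosome ends and in the mitochondrial genome, and the lowest included ribosomal protein and histone genes (n = 3 arrays). DLD3 (YEL071W), a D-lactate dehydrogenase gene 7 genes from an end of chromosome V, was higher at a log2 ratio of 3.46 (SE 0.11, adjusted p = 9.86e-09). PTR2 (YKR093W), a peptide transporter gene 15 genes from an end of chromosome XI, was higher by 7.98-fold at 3.00 (SE 0.087, adjusted p = 6.63e-09). CSS1 (YIL169C), 5 genes from an end of chromosome IX, was at 2.95 (SE 0.079), YAT1 (YAR035W), a carnitine acetyltransferase gene 8 genes from an end of chromosome I, at 2.95 (SE 0.15), and ATP8 (Q0080), a mitochondrially encoded subunit of ATP synthase, at 3.05 (SE 0.24). Lowest were SIM1 (YIL123W) at -1.69 (SE 0.11) and SUN4 (YNL066W) at -1.68 (SE 0.10), both of the SUN family of cell wall proteins. RPL4A (YBR031W) at -1.66 (SE 0.068) and RPL4B (YDR012W) at -1.66 (SE 0.068), near-identical copies of a ribosomal protein gene, and the histone H2B gene HTB2 (YBL002W) at -1.59 (SE 0.094) followed.

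Subtelomeric families at 120 min were higher by the largest list medians of that time. COS genes, with a median 4.53-fold higher, had 11 higher, 0 lower and 0 not passing of 11 (11 and 0 adjusted over the list alone), with median 2.18, adjusted p = 7.02e-07, and adjusted p = 0.0905 with an estimated correlation. Seripauperin (PAU) genes, a family of cell wall mannoprotein genes with a median 3.75-fold higher, had 26 higher, 1 lower and 2 not passing of 29 (26 and 1 adjusted over the list alone), with median 1.91, adjusted p = 9.12e-13, and adjusted p = 0.139 with an estimated correlation. YRF1 genes had 8 higher, 0 lower and 0 not passing of 8 (8 and 0 adjusted over the list alone). Their median was 1.18 (adjusted p = 1.82e-05, and adjusted p = 0.184 with an estimated correlation). Sugar, vitamin and flocculation families had 46 higher, 1 lower and 2 not passing of 49 (46 and 1 adjusted over the list alone), with median 1.09, adjusted p = 9.12e-13, and adjusted p = 0.0905 with an estimated correlation. Within 50 genes of an end lie 11 of 12 COS, 25 of 30 PAU, 8 of 8 YRF1 and 51 of 54 listed members of the mixed families.

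Of the lists lower at 120 min, ribosomal protein genes had 0 higher, 123 lower and 8 not passing of 131 (0 and 124 adjusted over the list alone), with median -0.71, adjusted p = 4.55e-25, and adjusted p = 0.163 with an estimated correlation. Histone genes had 0 higher, 11 lower and 0 not passing of 11 (0 and 11 adjusted over the list alone). The list median was -1.18 (adjusted p = 9.3e-07, and adjusted p = 0.0905 with an estimated correlation). The CLB2 cluster of G2/M genes had 5 higher, 17 lower and 8 not passing of 30 (5 and 17 adjusted over the list alone), with median -0.37, adjusted p = 0.00788, and adjusted p = 0.0905 with an estimated correlation. Sterol biosynthesis genes had 2 higher, 17 lower and 5 not passing of 24 (2 and 17 adjusted over the list alone), with median -0.38, adjusted p = 0.0196, and adjusted p = 0.33 with an estimated correlation. G1/S genes had 6 higher, 19 lower and 16 not passing of 41 (6 and 19 adjusted over the list alone), with median -0.16, adjusted p = 0.0326, and adjusted p = 0.405 with an estimated correlation. This call ended without 30 min replicate 2 (adjusted p = 0.0545), with median centring (0.0887) and in the authors' table (0.299), as did the G2/M call in that table (0.0776). Ribosome biogenesis genes did not pass, with 30 higher, 48 lower and 36 not passing of 114 (31 and 49 adjusted over the list alone) and median -0.09, adjusted p = 0.202.

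Stress and metabolic lists were higher at 120 min. Stress response genes had 50 higher, 3 lower and 12 not passing of 65 (50 and 3 adjusted over the list alone). These genes had a median of 0.54 (adjusted p = 3.28e-10, and adjusted p = 0.0905 with an estimated correlation). Heat shock proteins had 19 higher, 3 lower and 9 not passing of 31 (19 and 3 adjusted over the list alone), with median 0.38, adjusted p = 0.000982, and adjusted p = 0.3 with an estimated correlation. The call ended with median centring (median 0.01, adjusted p = 0.629) and in the authors' table (0.09 and 0.181). Quiescent-cell genes had 13 higher, 1 lower and 3 not passing of 17 (13 and 1 adjusted over the list alone), with median 0.92, adjusted p = 3.15e-05, and adjusted p = 0.145 with an estimated correlation. Mating genes and MATa-specific genes had 14 higher, 1 lower and 4 not passing of 19 (15 and 1 adjusted over the list alone). The median of the list was 0.53 (adjusted p = 3.15e-05, and adjusted p = 0.0905 with an estimated correlation). Respiration genes had 29 higher, 5 lower and 13 not passing of 47 (29 and 5 adjusted over the list alone), with median 0.32, adjusted p = 0.00186, and adjusted p = 0.405 with an estimated correlation. The call ended with median centring (median 0.10, adjusted p = 0.0884). Gluconeogenesis genes had 13 higher, 1 lower and 8 not passing of 22 (13 and 1 adjusted over the list alone), with median 0.36, adjusted p = 0.00414, and adjusted p = 0.266 with an estimated correlation. The call ended in the authors' table (adjusted p = 0.167). Glycolysis genes had 15 higher, 5 lower and 3 not passing of 23 (16 and 5 adjusted over the list alone), with median 0.40, adjusted p = 0.0119, and adjusted p = 0.405 with an estimated correlation, and their median was again negative with median centring, no normalization and the authors' table. Without the chromosome IV run the glycolysis call ended (adjusted p = 0.0744).

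Nutrient lists completed the calls at 120 min. Methionine and sulfur genes had 14 higher, 4 lower and 7 not passing of 25 (14 and 4 adjusted over the list alone). Their median was 0.35 (adjusted p = 0.0138, and adjusted p = 0.266 with an estimated correlation). The call ended in the authors' table (median 0.04, adjusted p = 0.285). Proteasome genes had 17 higher, 5 lower and 12 not passing of 34 (18 and 6 adjusted over the list alone), with median 0.18, adjusted p = 0.0326, and 0.285 with an estimated correlation. The call ended with median centring (median 0.03, adjusted p = 0.637) and in the authors' table (0.10 and 0.111). Iron and copper uptake genes had 14 higher, 6 lower and 6 not passing of 26 (14 and 6 adjusted over the list alone), with median 0.29, adjusted p = 0.0423, and 0.32 with an estimated correlation. This call ended without 0 min replicate 1 (adjusted p = 0.0504), 120 min replicate 1 (0.0618) or any one 30 min array (0.0511 to 0.0656), and in the authors' table (0.506). The 120 min medians ranged from -1.35 to -0.58 for ribosomal protein genes, -0.58 to -0.30 for G2/M genes, -0.60 to -0.31 for sterol genes, -0.25 to -0.09 for G1/S genes, and from 0.34 to 0.55 for stress genes, 0.43 to 0.80 for mating genes and 0.60 to 1.18 for YRF1 genes. In all, 3831 genes passed at 120 min, 1908 higher and 1923 lower, of which 397 were higher and 88 lower by more than 2-fold.

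**Figure D1:**
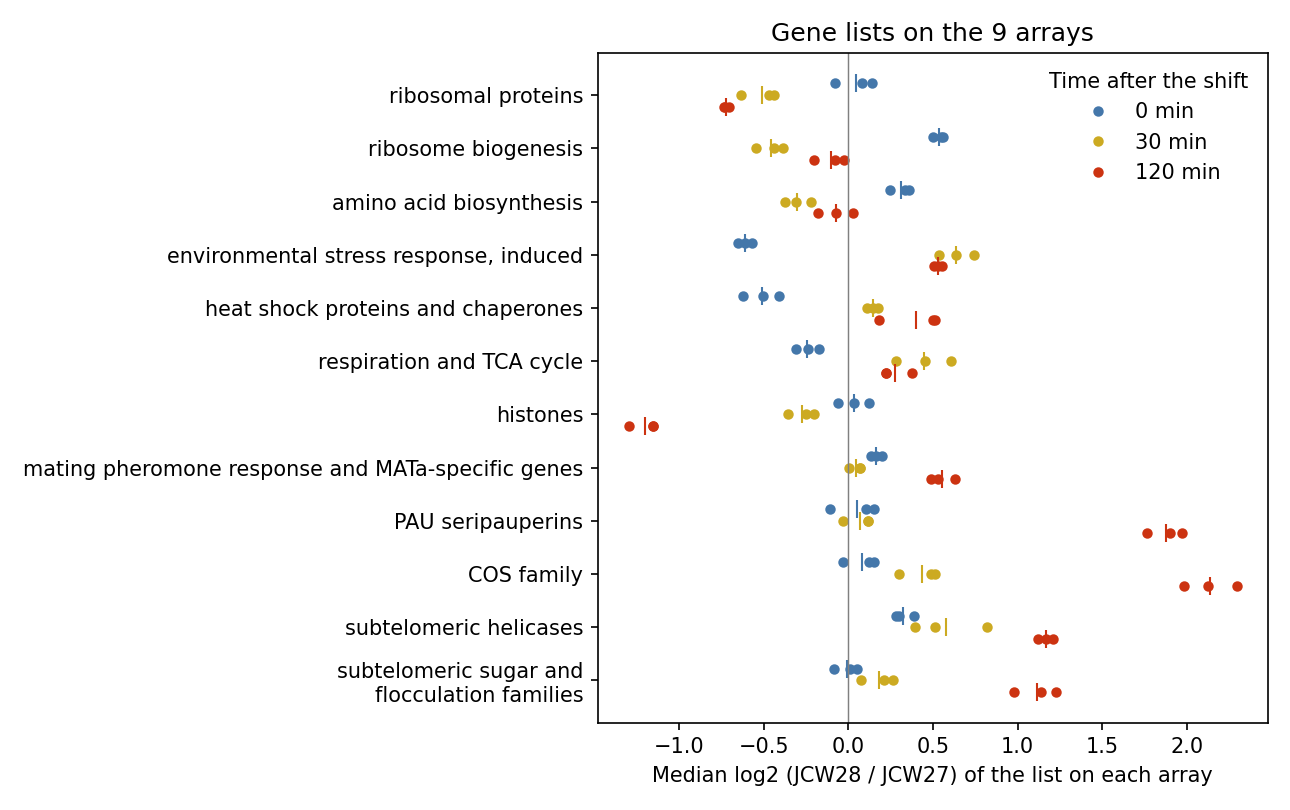
Median log2 strain ratio (JCW28 over JCW27) of the genes of each named list on each of the 9 arrays, by time. Ribosome biogenesis genes lay above 0 at 0 min and below it at 30 min, with list medians of 0.54 and -0.49, and COS genes reached a median of 2.18 at 120 min.

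From 0 to 30 min, the change in strain ratio addresses the early response to inactivation of top2-4, with constant dye effects cancelled (n = 3 arrays per time). HXK1 rose by 7.45-fold, TMA10 (YLR327C), a ribosome-associated protein gene, by 5.56-fold and TSL1 by 4.42-fold. DBP2 (YNL112W), an RNA helicase gene, fell by 4.15-fold, RNR1 by 3.46-fold and RPA49 (YNL248C), a subunit of RNA polymerase I, by 3.26-fold. On the log2 scale the change was 2.90 (SE 0.11, adjusted p = 5.89e-07) for HXK1, 2.47 (SE 0.12, adjusted p = 1.18e-06) for TMA10 and -2.05 (SE 0.14, adjusted p = 3.97e-06) for DBP2. The other largest rises were EGO4 (YNR034W-A) at 2.25 (SE 0.16) and YLR311C at 2.17 (SE 0.65), which was 1.17 without 30 min replicate 2 and did not pass without 0 min replicate 1 (adjusted p = 0.0589). The other largest falls were MAE1 (YKL029C), the malic enzyme gene, at -1.77 (SE 0.17) and YMC2 (YBR104W), a mitochondrial carrier gene, at -1.70 (SE 0.16). Each of these genes had its 3 values at one time above its 3 at the other.

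Growth gene ratios fell from 0 to 30 min. Of the ribosome biogenesis genes, 0 of 114 rose, 106 fell and 8 did not pass, against 0 and 111 adjusted over the list alone. Their median change was -1.02, a 2.03-fold fall (adjusted p = 9.76e-35), and the call held at adjusted p = 0.0324 with an estimated correlation. Members with the smallest p were HAS1 (YMR290C) at -1.18 (SE 0.075), DBP2, DHR2 (YKL078W) at -1.36 (SE 0.092) and NOG1 (YPL093W) at -1.38 (SE 0.093). For RNA polymerase I and III subunits, 1 of 36 rose, 21 fell and 14 did not pass, against 2 and 24 adjusted over the list alone (median -0.45, adjusted p = 2.52e-06), and the call held at adjusted p = 0.0197 with an estimated correlation. RPA135 (YPR010C) fell by 2.81-fold, RPC19 (YNL113W) by 2.05-fold and RPA12 (YJR063W) by 2.19-fold. Among Gcn4 targets, 1 of 49 rose, 39 fell and 9 did not pass, against 1 and 41 adjusted over the list alone (median -0.61, adjusted p = 1.1e-14), and the call held at adjusted p = 0.0324 with an estimated correlation. HIS1 (YER055C) fell by 3.04-fold, HOM3 (YER052C) by 2.90-fold, and TRP4 (YDR354W), in the chromosome IV run, by 2.51-fold. Of ribosomal protein genes, 0 of 131 rose, 119 fell and 12 did not pass, against 0 and 122 adjusted over the list alone (median -0.56, adjusted p = 1.02e-22), with adjusted p = 0.138 with an estimated correlation.

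Stress and carbon gene ratios rose from 0 to 30 min. Of the Msn2 and Msn4 stress genes, 61 of 65 rose, 1 fell and 3 did not pass, against 62 and 1 adjusted over the list alone. Their median rose 2.40-fold (median log2 change 1.27, adjusted p = 9.15e-30), and the call held at adjusted p = 0.0197 with an estimated correlation. Besides HXK1, GPH1 (YPR160W), glycogen phosphorylase, rose 3.93-fold, MSC1 (YML128C) 3.65-fold and RTN2 (YDL204W) 3.54-fold. Of heat shock genes, 21 of 31 rose, 1 fell and 9 did not pass, against 24 and 1 adjusted over the list alone (median 0.53, adjusted p = 5.47e-08), with adjusted p = 0.0994 with an estimated correlation. HSP26 (YBR072W) rose 4.27-fold. Of quiescent-cell genes, 14 of 17 rose, 0 fell and 3 did not pass, against 15 and 0 adjusted over the list alone (median 1.51, adjusted p = 6.14e-09), with adjusted p = 0.061 with an estimated correlation. Of respiration genes, 40 of 47 rose, 0 fell and 7 did not pass, against 43 and 0 adjusted over the list alone (median 0.61, adjusted p = 8.5e-14), with adjusted p = 0.0994 with an estimated correlation. The succinate dehydrogenase gene SDH1 (YKL148C) rose 2.59-fold.

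Gluconeogenesis and fatty acid oxidation genes had 17 rising, 0 falling and 5 not passing of 22 (19 and 0 adjusted over the list alone), with median 0.53, adjusted p = 4.1e-07, and adjusted p = 0.0783 with an estimated correlation. Glycolysis and fermentation genes had 12 rising, 0 falling and 11 not passing of 23 (12 and 0 adjusted over the list alone). The list median was 0.31 (adjusted p = 0.000491, and adjusted p = 0.276 with an estimated correlation). The call ended with median centring (median 0.08, adjusted p = 0.216) and in the authors' table (0.05 and 0.209). The 4 with the smallest p were hexose transporter genes, HXT6 at 1.90 (SE 0.095), HXT3 (YDR345C) at 1.41 (SE 0.11), HXT7 (YDR342C) at 1.61 (SE 0.13) and HXT2 (YMR011W) at 1.31 (SE 0.12), of which HXT6, HXT3 and HXT7 lie in the chromosome IV run. Galactose genes had 4 rising, 0 falling and 6 not passing of 10 (4 and 0 adjusted over the list alone), with median 0.21, adjusted p = 0.0152, and adjusted p = 0.0994 with an estimated correlation. GCY1 (YOR120W) rose 3.19-fold and PGM2 (YMR105C) 3.04-fold, and 2 of the 10 genes are also on other lists. Proteasome genes had 21 rising, 0 falling and 13 not passing of 34 (24 and 0 adjusted over the list alone), with median 0.34, adjusted p = 1.11e-05, and adjusted p = 0.061 with an estimated correlation.

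Cell cycle, sterol and subtelomeric lists passed as well from 0 to 30 min. G1/S genes had 0 rising, 22 falling and 19 not passing of 41 (0 and 24 adjusted over the list alone). These genes had a median of -0.33 (adjusted p = 1.87e-06, and adjusted p = 0.0994 with an estimated correlation). Histone genes had 0 rising, 5 falling and 6 not passing of 11 (0 and 5 adjusted over the list alone), with median -0.23, adjusted p = 0.019, and adjusted p = 0.269 with an estimated correlation. Sterol genes had 2 rising, 9 falling and 13 not passing of 24 (2 and 9 adjusted over the list alone), with median -0.27, adjusted p = 0.0312, and adjusted p = 0.353 with an estimated correlation. COS genes had 7 rising, 0 falling and 4 not passing of 11 (7 and 0 adjusted over the list alone), with median 0.42, adjusted p = 0.0121, and adjusted p = 0.238 with an estimated correlation. YRF1 genes had 3 rising, 0 falling and 5 not passing of 8 (7 and 0 adjusted over the list alone), with median 0.30, adjusted p = 0.031, and adjusted p = 0.419 with an estimated correlation. The sugar, vitamin and flocculation families had 13 rising, 6 falling and 30 not passing of 49 (13 and 6 adjusted over the list alone), with median 0.23, adjusted p = 0.0354, and adjusted p = 0.524 with an estimated correlation.

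Calls on small lists from 0 to 30 min depended on single arrays and on the processing. The sterol call ended without 0 min replicate 1 (adjusted p = 0.0538) or 30 min replicate 3 (0.0884), and its median was -0.16 without 0 min replicate 3. The YRF1 call ended without 30 min replicate 2 (adjusted p = 0.118). The call on the mixed subtelomeric families ended without 0 min replicate 1 (adjusted p = 0.0952) or 30 min replicate 3 (0.0877). In the authors' table the sterol (0.0664), YRF1 (0.173) and mixed family (0.242) calls ended, and the YRF1 call with median centring (0.216). The medians ranged from -0.71 to -0.39 for RNA polymerase I and III, -0.57 to -0.26 for G1/S genes, -0.43 to -0.17 for histone genes, -0.33 to -0.17 for sterol genes. They ranged from 0.16 to 0.31 for YRF1 genes, 0.17 to 1.12 for galactose genes and 0.47 to 1.14 for gluconeogenesis. In all, 2400 genes changed from 0 to 30 min, 1151 up and 1249 down, 159 and 158 of them by more than 2-fold.

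From 0 to 120 min, the comparison asks how the strain ratio changed after long inactivation of topoisomerase II (n = 3 arrays per time). PTR2 rose 10.9-fold, YAT1 9.72-fold and CSS1 9.64-fold, all within 15 genes of a chromosome end. HXK1, 4 genes from an end of chromosome VI, rose 8.83-fold and the small heat shock gene HSP26 7.93-fold. The histone gene HTB2 fell 4.08-fold, YEF3 (YLR249W), translation elongation factor 3, 3.48-fold and OLE1 (YGL055W), the fatty acid desaturase gene, 3.27-fold. The log2 change was 3.44 (SE 0.12, adjusted p = 4.61e-08) for PTR2, 3.27 (SE 0.11, adjusted p = 4.36e-08) for CSS1, -2.03 (SE 0.13, adjusted p = 1.62e-06) for HTB2 and -1.80 (SE 0.17, adjusted p = 1.71e-05) for YEF3. Other rises were 3.28 (SE 0.22) for YAT1, 3.14 (SE 0.11) for HXK1, 2.99 (SE 0.13) for HSP26, 2.80 (SE 0.16) for DLD3 and 2.73 (SE 0.075) for YML131W, 3 genes from an end of chromosome XIII. The mitochondrial genes COB (Q0105), for cytochrome b, and ATP6 (Q0085) rose by 3.04 (SE 0.24) and 3.01 (SE 0.45), and YGL088W by 3.18 (SE 0.74). Other falls were -1.77 (SE 0.15) for the H2A gene HTA1 (YDR225W), -1.75 (SE 0.096) for RPL4A, -1.72 (SE 0.096) for RPL4B, -1.71 (SE 0.11) for LIA1 (YJR070C), -1.71 (SE 0.13) for OLE1, -1.65 (SE 0.14) for the nucleolar gene NSR1 (YGR159C) and -1.63 (SE 0.16) for SIM1. Each of these genes had its 3 values at one time above its 3 at the other.

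Families at chromosome ends rose from 0 to 120 min. Of the PAU genes, 26 of 29 rose, 0 fell and 3 did not pass, against 28 and 0 adjusted over the list alone, and their median rose 3.58-fold (median 1.84, adjusted p = 1.31e-15), with adjusted p = 0.0724 with an estimated correlation. Of the COS genes, 9 of 11 rose, 0 fell and 2 did not pass, against 10 and 0 adjusted over the list alone, and their median rose 3.96-fold (median 1.99, adjusted p = 3.66e-07), with adjusted p = 0.0724 with an estimated correlation. Of the mixed sugar, vitamin and flocculation families, 45 of 49 rose, 1 fell and 3 did not pass, against 46 and 1 adjusted over the list alone (median 1.23, adjusted p = 1.34e-12), with adjusted p = 0.0724 with an estimated correlation. Of the YRF1 genes, 8 of 8 rose, 0 fell and 0 did not pass, against 8 and 0 adjusted over the list alone (median 0.90, adjusted p = 8.16e-05), with adjusted p = 0.154 with an estimated correlation.

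Ribosome and growth genes fell from 0 to 120 min. Of ribosomal protein genes, 0 of 131 rose, 118 fell and 13 did not pass, against 0 and 121 adjusted over the list alone (median -0.78, adjusted p = 1.72e-24), with adjusted p = 0.109 with an estimated correlation. Of ribosome biogenesis genes, 2 of 114 rose, 91 fell and 21 did not pass, against 2 and 93 adjusted over the list alone (median -0.66, adjusted p = 6.14e-15), with adjusted p = 0.0735 with an estimated correlation. Of RNA polymerase I and III subunits, 1 of 36 rose, 17 fell and 18 did not pass, against 1 and 16 adjusted over the list alone (median -0.29, adjusted p = 0.00278), with adjusted p = 0.0724 with an estimated correlation. Of Gcn4 targets, 6 of 49 rose, 31 fell and 12 did not pass, against 8 and 31 adjusted over the list alone (median -0.46, adjusted p = 0.000306), with adjusted p = 0.154 with an estimated correlation.

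Histone and cell cycle genes fell from 0 to 120 min. Of histone genes, 0 of 11 rose, 10 fell and 1 did not pass, against 0 and 10 adjusted over the list alone (median -1.28, adjusted p = 1.2e-06), with adjusted p = 0.0724 with an estimated correlation. Of the G2/M cluster, 4 of 30 rose, 17 fell and 9 did not pass, against 4 and 18 adjusted over the list alone (median -0.39, adjusted p = 0.00775), with adjusted p = 0.0724 with an estimated correlation. Of G1/S genes, 2 of 41 rose, 17 fell and 22 did not pass, against 2 and 17 adjusted over the list alone (median -0.21, adjusted p = 0.028), with adjusted p = 0.315 with an estimated correlation. This call ended without 0 min replicate 1 (adjusted p = 0.0726), with median centring (0.057) and in the authors' table (0.202), as did the G2/M call in that table (0.202). Of sterol genes, 2 of 24 rose, 15 fell and 7 did not pass, against 2 and 16 adjusted over the list alone (median -0.42, adjusted p = 0.00288), with adjusted p = 0.19 with an estimated correlation.

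Stress and carbon gene ratios rose from 0 to 120 min. Of the Msn2 and Msn4 genes, 60 of 65 rose, 0 fell and 5 did not pass, against 60 and 1 adjusted over the list alone (median 1.23, adjusted p = 3.7e-23), with adjusted p = 0.0529 with an estimated correlation. HSP12 (YFL014W) rose 5.77-fold. Of heat shock genes, 25 of 31 rose, 0 fell and 6 did not pass, against 25 and 0 adjusted over the list alone (median 0.88, adjusted p = 2.82e-09), with adjusted p = 0.0735 with an estimated correlation. HSP42 rose 6.23-fold. Of quiescent-cell genes, 13 of 17 rose, 0 fell and 4 did not pass, against 15 and 0 adjusted over the list alone (median 1.37, adjusted p = 2.55e-07), with adjusted p = 0.0724 with an estimated correlation. Of respiration genes, 30 of 47 rose, 3 fell and 14 did not pass, against 32 and 3 adjusted over the list alone (median 0.46, adjusted p = 1.24e-06), with adjusted p = 0.196 with an estimated correlation. Of gluconeogenesis genes, 13 of 22 rose, 0 fell and 9 did not pass, against 14 and 0 adjusted over the list alone (median 0.47, adjusted p = 0.000142), with adjusted p = 0.109 with an estimated correlation.

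Glycolysis genes had 15 rising, 5 falling and 3 not passing of 23 (15 and 5 adjusted over the list alone) from 0 to 120 min, with median 0.52, adjusted p = 0.028, and adjusted p = 0.41 with an estimated correlation. The call ended with median centring (median 0.13, adjusted p = 0.862), in the authors' table (0.13 and 0.589) and without the chromosome IV run (adjusted p = 0.158). Galactose genes had 6 rising, 0 falling and 4 not passing of 10 (6 and 0 adjusted over the list alone), with median 0.36, adjusted p = 0.0159, and 0.0943 with an estimated correlation. The test used the 7 galactose genes on all 9 arrays (median 0.63), and without 30 min replicate 2 another set (0.36, adjusted p = 0.0175). Mating and MATa-specific genes had 13 rising, 1 falling and 5 not passing of 19 (14 and 3 adjusted over the list alone), with median 0.54, adjusted p = 0.00161, and 0.0724 with an estimated correlation. Proteasome genes had 16 rising, 3 falling and 15 not passing of 34 (16 and 3 adjusted over the list alone), with median 0.19, adjusted p = 0.0196, and 0.183 with an estimated correlation. Methionine and sulfur genes had 12 rising, 5 falling and 8 not passing of 25 (13 and 5 adjusted over the list alone), with median 0.27, adjusted p = 0.0246, and 0.197 with an estimated correlation, and their median was -0.05 in the authors' table, where the call ended (adjusted p = 0.456). The members with the smallest p were the permease genes SAM3 (YPL274W) at 1.99 (SE 0.13), MUP3 (YHL036W) at 1.41 (SE 0.10) and MMP1 (YLL061W) at 1.55 (SE 0.13), which lie 8, 16 and 7 genes from an end, and MET2 (YNL277W) at 1.22 (SE 0.11). Iron and copper genes had 14 rising, 5 falling and 7 not passing of 26 (15 and 5 adjusted over the list alone), with median 0.34, adjusted p = 0.0357, and 0.235 with an estimated correlation. The iron call ended without 0 min replicate 1 (adjusted p = 0.0648) or 120 min replicate 1 (0.0515), with median centring (0.0508) and in the authors' table (0.42), and the proteasome call with median centring (0.0853). The medians ranged from 0.22 to 0.39 for iron and copper, 0.32 to 1.05 for gluconeogenesis, 0.34 to 1.19 for galactose genes, -0.05 to 0.50 for methionine and sulfur and 0.49 to 0.91 for YRF1 genes.

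Other lists did not pass in the change from 0 to 120 min. Topoisomerase and supercoil genes had 2 rising, 7 falling and 7 not passing of 16 (2 and 7 adjusted over the list alone), with median -0.16, adjusted p = 0.318. The adjusted p was 0.133 for DNA damage, 0.441 for phosphate, 0.335 for cell wall integrity, 0.284 for RNA polymerase II and 0.318 for meiosis genes. It was 0.767 for chromatin genes, whose median of -0.02 and mean of 0.01 differed in sign. For M/G1 genes it was 0.584, with a median of -0.17 and a direction up by fry. Too few of the MATalpha-specific genes were measured on all 9 arrays for a test, and of 6 measured, 2 rose and 1 fell. In all, 3152 genes changed from 0 to 120 min, 1570 up and 1582 down, of which 353 rose and 150 fell by more than 2-fold.

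Between 30 and 120 min, the comparison separates late changes from the early ones (n = 3 arrays per time). DLD3 rose most, PTR2 rose 7.93-fold, YAT1 7.55-fold and ERO1 (YML130C), the oxidase of protein folding in the endoplasmic reticulum that lies 4 genes from an end of chromosome XIII, 6.45-fold. The histone genes HTA1 and HTB2 fell 3.26-fold and 2.67-fold, and ADR1 (YDR216W), a transcription factor for growth without glucose, 2.99-fold. The log2 change was 3.91 (SE 0.16, adjusted p = 3.28e-07) for DLD3, 2.69 (SE 0.12, adjusted p = 3.73e-07) for ERO1, -1.70 (SE 0.15, adjusted p = 1.82e-05) for HTA1 and -1.58 (SE 0.12, adjusted p = 6.71e-06) for ADR1. YGL088W rose by 3.60 (SE 0.74) and IZH4 (YOL101C) changed by -1.53 (SE 0.12). VTC2 (YFL004W) changed by -1.55 (SE 0.56), a value that rested on 30 min replicate 2 and was -0.66 without it, and the call was lost when any single array of 0 or 120 min was left out (adjusted p = 0.0558 to 0.12).

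Subtelomeric families rose between 30 and 120 min. Of the PAU genes, 25 of 29 rose, 1 fell and 3 did not pass, against 25 and 1 adjusted over the list alone (median 1.78, adjusted p = 6.98e-18), with adjusted p = 0.0974 with an estimated correlation. Of the COS genes, 9 of 11 rose, 0 fell and 2 did not pass, against 9 and 0 adjusted over the list alone (median 1.56, adjusted p = 4e-07), with adjusted p = 0.0974 with an estimated correlation. Of the mixed families, 41 of 49 rose, 1 fell and 7 did not pass, against 43 and 1 adjusted over the list alone (median 0.81, adjusted p = 1.71e-13), with adjusted p = 0.0974 with an estimated correlation. Of the YRF1 genes, 8 of 8 rose, 0 fell and 0 did not pass, against 8 and 0 adjusted over the list alone (median 0.63, adjusted p = 0.000243), with adjusted p = 0.264 with an estimated correlation.

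Growth and amino acid genes moved in different directions between 30 and 120 min. Of ribosome biogenesis genes, 58 of 114 rose, 4 fell and 52 did not pass, against 60 and 4 adjusted over the list alone (median 0.34, adjusted p = 1.22e-07), with adjusted p = 0.258 with an estimated correlation. Of ribosomal protein genes, 1 of 131 rose, 47 fell and 83 did not pass, against 1 and 46 adjusted over the list alone (median -0.19, adjusted p = 7.41e-06), with adjusted p = 0.627 with an estimated correlation. Of Gcn4 targets, 25 of 49 rose, 2 fell and 22 did not pass, against 25 and 2 adjusted over the list alone (median 0.26, adjusted p = 4.9e-05), with adjusted p = 0.181 with an estimated correlation. Of methionine and sulfur genes, 14 of 25 rose, 2 fell and 9 did not pass, against 15 and 2 adjusted over the list alone (median 0.34, adjusted p = 0.000104, and 0.124 with an estimated correlation). Of iron and copper genes, 14 of 26 rose, 3 fell and 9 did not pass, against 14 and 3 adjusted over the list alone (median 0.36, adjusted p = 0.00192, and 0.181 with an estimated correlation).

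Histone genes had 0 rising, 10 falling and 1 not passing of 11 (0 and 10 adjusted over the list alone) between 30 and 120 min, with median -0.65, adjusted p = 2.23e-06, and adjusted p = 0.0974 with an estimated correlation. Mating genes had 11 rising, 1 falling and 7 not passing of 19 (12 and 2 adjusted over the list alone), with median 0.71, adjusted p = 2.68e-05, and adjusted p = 0.0843 with an estimated correlation. Heat shock genes had 16 rising, 1 falling and 14 not passing of 31 (16 and 1 adjusted over the list alone), with median 0.32, adjusted p = 0.00624, and adjusted p = 0.443 with an estimated correlation. G1/S genes had 15 rising, 3 falling and 23 not passing of 41 (15 and 3 adjusted over the list alone), with median 0.18, adjusted p = 0.0136, and adjusted p = 0.419 with an estimated correlation, a call that ended without 30 min replicate 3 (adjusted p = 0.0771). Stress response genes did not pass, with 19 rising, 17 falling and 29 not passing of 65 (19 and 17 adjusted over the list alone) and median -0.04, adjusted p = 0.977. The medians ranged from -0.36 to -0.11 for ribosomal protein genes, 0.21 to 0.44 for ribosome biogenesis, 0.12 to 0.33 for heat shock genes, -1.02 to -0.49 for histone genes, 0.17 to 0.32 for G1/S genes, 0.12 to 0.26 for Gcn4 targets, 0.22 to 0.40 for methionine and sulfur, 0.23 to 0.43 for iron and copper and 0.34 to 0.65 for YRF1 genes. In all, 2476 genes changed between 30 and 120 min, 1248 up and 1228 down, of which 224 rose and 31 fell by more than 2-fold.

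In strain ratio, genes near chromosome ends rose relative to interior genes by 120 min. The median change from 0 to 120 min was 0.32 for the 1436 genes within 50 genes of an end and -0.10 for the 4096 interior genes, a difference of 0.42 on the log2 scale. Of the near genes 717 (49.9%) rose and 193 (13.4%) fell, against 778 (19.0%) and 1324 (32.3%) of the interior genes. The 280 genes closest to the ends, at positions 1 to 10, had a median change of 0.84, and 77.5% of them rose. The median change was 0.46 at positions 11 to 20, 0.24 at 21 to 30 and 0.10 at 31 to 40. Over the measured genes among the 10 outermost of each end, all 32 ends had a positive median change, from 0.065 to 1.67, and from 0 to 30 min 23 of 32 did, a count that was not tested. On chromosome I, which has no gene more than 47 from an end, 84 genes had a median change of 0.12, with 28 rising and 20 falling.

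The difference between near and interior genes was positive on 15 of 15 chromosomes from 0 to 120 min, with a mean of 0.398 ± 0.139 (SD across chromosomes, n = 15) and an exact sign-flip p of 6.1e-05, the smallest this test can give (adjusted p = 0.000122 over 6 comparisons). No circular permutation of the gene order out of 10000 was as large (permutation p = 1e-04, the smallest possible). Camera with an estimated correlation gave p = 0.000275. Per array, the difference averaged 0.016 ± 0.015 at 0 min, 0.020 ± 0.0057 at 30 min and 0.447 ± 0.027 at 120 min (SD, n = 3), and the exact permutation test of 0 against 120 min gave p = 0.1, the smallest it can reach. From 30 to 120 min the difference was again 0.42, positive on 15 of 15 chromosomes (0.0086 to 0.617; exact sign-flip p = 6.1e-05). From 0 to 30 min it was 0.0073, positive on 8 of 15 chromosomes (exact sign-flip p = 0.787, exact permutation p = 0.8). In the strain ratios it was 0.024 at 0 min (exact sign-flip p = 0.481), 0.019 at 30 min (p = 0.842) and 0.44 at 120 min (p = 6.1e-05), where 863 near genes were higher and 215 lower, against 919 and 1624 interior genes. Scan day and time cannot be told apart, and with no strain free of TOPA the loss of topoisomerase II and the state of the DNA are not separated.

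**Figure D2:**
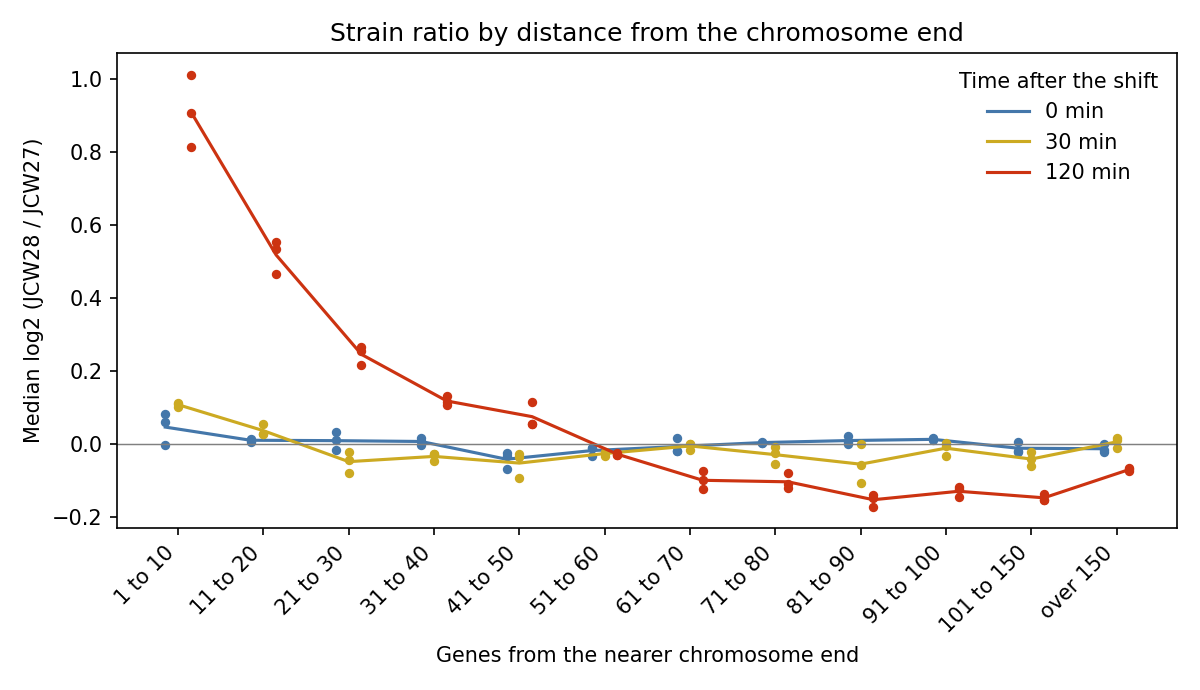
Median log2 strain ratio per array at 0, 30 and 120 min, and its mean, in bins by position from the nearer chromosome end. At 120 min the mean fell from 0.91 in the outermost bin to 0.12 at positions 31 to 40.

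**Figure D3:**
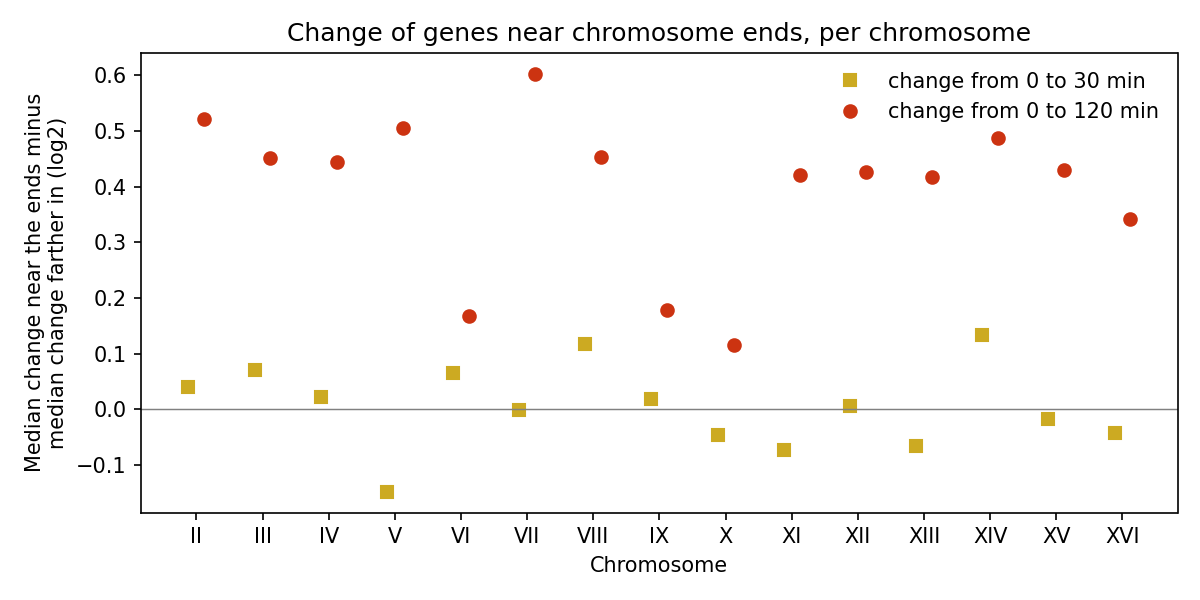
Difference in median log2 change between genes within 50 genes of an end and interior genes, one point per chromosome, for each change over time. From 0 to 120 min all 15 chromosomes lie above 0, and from 0 to 30 min 8 of 15 do.

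Gene length and the orientation of neighbours were described across genes, which are not independent replicates. Across 5532 genes the change from 0 to 120 min had a Spearman correlation of -0.267 with the number of genes from the end (circular permutation p = 0.0005, the smallest possible, adjusted p = 0.0015 over 15 relations). With coding length it was 0.0105 (circular permutation p = 0.41, adjusted p = 0.615), and with mean intensity -0.0317 (circular permutation p = 0.0005, adjusted p = 0.0015). Of the interior genes, 2129 converge with the next gene, and their median change was -0.14, against -0.06 for 1967 tandem genes, a difference of -0.079 (circular permutation p = 0.0005, adjusted p = 0.0015) that did not pass in the authors' table (-0.0734, adjusted p = 0.054). The difference for divergent genes was 0.0024 (circular permutation p = 0.67). The change from 0 to 30 min had a correlation of -0.116 with mean intensity (adjusted p = 0.0015). From 30 to 120 min it was 0.0665 with mean intensity (adjusted p = 0.0431), turning to -0.0643 with median centring, and 0.0311 with coding length (adjusted p = 0.03), which did not pass in the authors' table (0.0146).

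Genes that check the labels gave the following values. TOP1 is deleted in both strains, yet the spots of TOP1 (YOL006C) were above background on all 9 arrays in both, at -0.51, -0.39 and -0.85 at 0, 30 and 120 min. Its change from 0 to 120 min passed at -0.34 (SE 0.11, adjusted p = 0.0246) but not without 0 or 120 min replicate 1 or 3 (adjusted p = 0.0513 to 0.0787), and what these spots measure is unknown. TOP2 (YNL088W), present in both strains, stood at 0.24, -0.19 and -0.24, and TOP3 (YLR234W) at -0.26, -0.40 and -0.62. LEU2 (YCL018W), a selectable marker, stood at 0.38, 0.02 and -0.54, with signs at 0 and 30 min that turn under other scalings. URA3 (YEL021W) stood at -0.11, -0.43 and -0.23, and TRP1 (YDR007W) at 0.15, 0.40 and -0.22, negative at 30 min under median centring, no normalization and the authors' table. The a-factor genes MFA1 (YDR461W) and MFA2 (YNL145W) were higher at 120 min by 2.73-fold and 2.26-fold, and STE2 (YFL026W), the a-cell receptor gene, by 1.69-fold. STE3 (YKL178C), the receptor gene of the other mating type, stood at -0.12 and did not pass (adjusted p = 0.286). MF(ALPHA)1 (YPL187W) was not above background in either strain at 0 min, so no fold is given there, and was higher at 120 min at 0.59 (SE 0.089, adjusted p = 0.000318). HIS3 was measured on 2 arrays and not tested. At 0 min TOP2, TOP3 and STE3 did not pass without any one array of that time (adjusted p = 0.0530 to 0.210), STE2 without replicate 2 or 3 (0.12 and 0.228), and TOP3 and STE3 without some 120 min arrays (0.0508 to 0.0581). At 30 min MFA1 and STE2 did not pass without replicate 3 (0.0729 and 0.0538), and URA3 was -0.25 without replicate 2. At 120 min TOP2 did not pass without replicate 1 or 3 (0.15 and 0.0818), nor TRP1 without replicate 1 or 2 (0.12 and 0.0661).

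**Figure D4:**
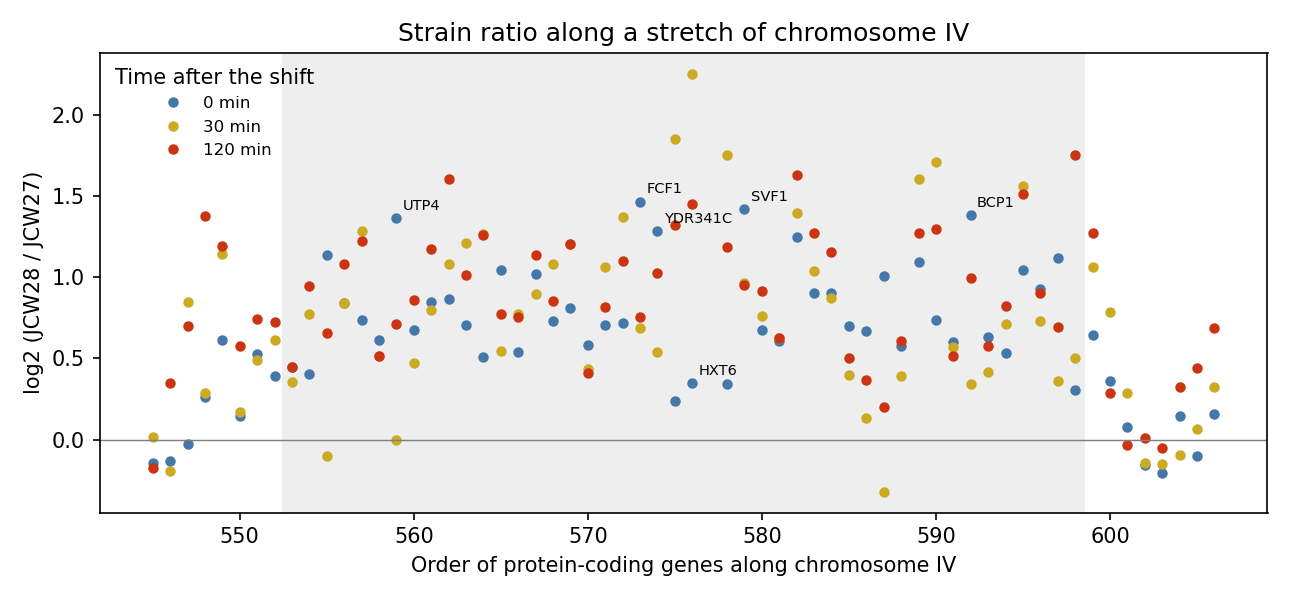
Mean log2 strain ratio at 0, 30 and 120 min of protein-coding genes in their order along a stretch of chromosome IV, with a run of 45 measured genes shaded. Of these genes 43, 40 and 45 were higher in JCW28 at 0, 30 and 120 min.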

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

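The tests of dim spots, of the stress response, of the copy number of chromosome XII before the shift, of an extra copy on chromosome IV and of the order of genes there were chosen only after the results were seen.

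Genes near chromosome ends rose against interior genes by 0.42 from 0 to 120 min and by 0.42 from 30 to 120 min, which stands out because the difference was 0.024 and 0.019 at 0 and 30 min, although the outermost genes had a positive median change from 0 to 30 min at 23 of 32 ends. Subtelomeric families that hybridise to each other do not account for it, since without those families and the 10 outermost genes of every end the difference was 0.332, positive on 14 of 15 chromosomes (1143 near genes, exact sign-flip p = 0.000122). A drift of dim spots would lift them, but the 352 negative control spots moved by -0.27 (exact permutation p = 0.1). On the 30 min arrays the Msn2 and Msn4 stress list had made 1.00 to 1.18 of its change from 0 to 120 min, and the ends at most 0.0234 of theirs. From 30 to 120 min 16 of 31 heat shock genes rose and 14 did not pass (adjusted p = 0.00624, and adjusted p = 0.443 with an estimated correlation), so a later heat shock response was not excluded. A late effect that depends on the distance to an end may therefore be at work, and positive supercoiling, the loss of topoisomerase II and the scan day stay open as its source.

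Interior genes of chromosome XII (396 genes) changed by -0.21 relative to the other chromosomes from 0 to 120 min (exact permutation p = 0.1, the smallest possible). A copy number difference from before the shift would be there at 0 min, when the farthest array stood at -0.0269, but one that arose later was not tested. Without ribosomal protein and ribosome biogenesis genes, 25 of the 396, the change was -0.22, and the next lowest chromosome stood at -0.15. Genes within 50 genes of the ribosomal DNA differed from the others by -0.0337 (circular permutation p = 0.76), which argues against a local effect of that region. Chromosome XII was picked out after the values of all chromosomes were seen. The 25 interior genes of chromosome VI moved by 0.34, and by 0.12 to 0.36 over the scaling and background settings, against -0.26 to -0.15 for chromosome XII, and the other chromosomes had an SD of 0.12 without both lists. An effect of the chromosome as a whole may remain, and top2-4 and supercoiling were not tested as its source.

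A run of 45 measured neighbours on chromosome IV was higher in JCW28 by 0.71 ± 0.058, 0.74 ± 0.044 and 0.93 ± 0.040 than the other interior genes of the chromosome at 0, 30 and 120 min (SD, n = 3). The run was picked by its 0 min ratios, so only the 30 and 120 min values are independent of that choice. At 0 min 45 windows of 11 genes had a median above 0.5, against at most 6 in 1000 shuffles of the gene order. Adjacent spots on the array that hold other genes stood at 0.0389, against 0.72 for the run's own spots, which lie in 13 of 48 print blocks. An extra copy of the segment in JCW28 would lift every array, and the lowest of the 30 and 120 min arrays stood at 0.70, so a candidate explanation is a duplication. FCF1, SVF1, BCP1, UTP4, YDR341C, TRP4, HXT3, HXT6 and HXT7 lie in the run, so their strain ratios need not reflect regulation.

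Some lists passed at both of 2 times with all 3 arrays on opposite sides of 0, and their change passed too. From 0 to 30 min these were ribosome biogenesis (-1.02), RNA polymerases I and III (-0.45), Gcn4 targets (-0.61), stress genes (1.27), respiration (0.61), gluconeogenesis (0.53) and quiescent-cell genes (1.51). From 0 to 120 min they were heat shock (0.88), stress (1.23), respiration (0.46), gluconeogenesis (0.47) and quiescent-cell genes (1.37). With an estimated correlation no list passed at both times, and only the first 4 changes held (adjusted p = 0.0197 to 0.0324), the others being lost (0.0529 to 0.196). In the authors' table the heat shock call at 120 min and the gluconeogenesis calls at all 3 times ended, and with median centring the heat shock and respiration calls at 120 min. Other lists whose median changed sign, such as galactose genes, did not pass at both times. Among single genes, 650 passed in opposite directions at 0 and 30 min with a change that also passed.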

How the results depend on the processing

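The gene-count distances from an end, the removal of the 10 outermost genes, the joint removal of 2 arrays and the removal of the chromosome IV run were chosen after seeing the data. Of 167 counts of genes under the alternatives, 165 lay within 1.5 times the reported ones. The exceptions were 1510 and 1363 genes at 0 min without 0 min replicate 2 and without 0 min replicate 3. With one array left out the counts ran from 1363 to 2841 at 0 min, 2676 to 3314 at 30 min, 3202 to 4077 at 120 min, 1885 to 2518 from 0 to 30 min, 2583 to 3496 from 0 to 120 min, 1980 to 2531 from 30 to 120 min, and 3329 to 4079 by the F test.

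Calls on lists depended on the assumed correlation between genes. With an estimated one, 1, 0 and 0 lists passed at 0, 30 and 120 min and 4, 0 and 0 in the changes from 0 to 30, 0 to 120 and 30 to 120 min, where fry gave 16, 25, 28, 25, 28 and 19. The authors' table gave 11 lists at 120 min. With one array left out the numbers of lists were 10 to 10, 14 to 16, 17 to 19, 16 to 19, 21 to 24 and 12 to 15, in the same order. Of 1565 values for single lists, with medians over genes on all 9 arrays, 154 no longer passed and 4 reversed in the direction of the test, all for glycolysis: -0.20 and -0.070 at 30 min and -0.35 and -0.27 at 120 min, with median centring and the authors' table. Among the 154, the median of iron genes at 120 min turned to -0.04 in the authors' table. The cause was not tested. Without the 2 least correlated arrays together, the calls on galactose genes at 0 min, G1/S, iron and proteasome genes at 120 min, COS and YRF1 genes from 0 to 30 min, and G1/S and iron genes from 0 to 120 min ended (adjusted p = 0.056 to 0.116).

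The difference near chromosome ends from 0 to 120 min ran from 0.310 with 75 genes to 0.609 with 25 genes over the alternatives (largest exact sign-flip p = 0.000122), and from 0.416 to 0.446 with one array left out. The latter range was 0.441 to 0.466 at 120 min, 0.409 to 0.431 from 30 to 120 min, 0.0098 to 0.026 at 0 min, 0.0086 to 0.019 at 30 min and -0.0018 to 0.018 from 0 to 30 min. Within 25 genes it passed at 30 min (0.055, exact sign-flip p = 0.0452). In the authors' table the convergent difference was -0.0734 from 0 to 120 min (adjusted p = 0.054) and -0.0481 from 30 to 120 min (0.0625), and from 30 to 120 min the correlations were 0.0146 with coding length and 0.0108 with intensity, none passing. With median centring the last was -0.0643. The cause was not tested.

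Of 5636 values for named genes, 17 reversed, with the cause not tested. LEU2 at 0 min was -0.0069, -0.0047 and -0.0057 with median centring, no normalization and print-tip loess, and 0.025 from 0 to 30 min with print-tip loess. At 30 min, with median centring, no normalization and the authors' table, LEU2 was -0.57, -0.53 and -0.48, TRP1 -0.22, -0.17 and -0.11, MFA1 -0.19, -0.15 and -0.17, and MFA2 -0.38, -0.34 and -0.33. MF(ALPHA)1 at 30 min was 0.45 with no normalization. A block for scan day was not run, since scan day and time cannot be told apart. Signal over background limits genes such as YDR250C and YOR053W to lower bounds.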

Other observations

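The splits were planned, whereas the mitochondrial genes were picked after their values were seen and were not tested as a list. Of 27 genes encoded in the mitochondrial genome, 10, 18 and 21 were higher in JCW28 at 0, 30 and 120 min and 0 were lower, with medians of 0.51, 0.97 and 1.57. From 0 to 120 min 16 of them rose, with a median change of 0.94 or 1.92-fold, which was 0.45 with scaling between arrays, and per-array medians ran from 0.19 to 1.83.

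Of 100 groupings of the 9 arrays, the real one gave 3856 genes by the F test and the highest random one 1231. That share, 1 of 100, is under 0.05 but the smallest possible, and scan day follows time. For the changes over time, 1 of 10 splits of 6 arrays reached the real 2400, 3152 and 2476 genes, and the highest other gave 0, but 10 are too few for a share under 0.05. For the strain differences at 0, 30 and 120 min, 1 of 4 assignments reached the real 2409, 3323 and 3831, the highest others gave 0, 1 and 0, and 4 are too few as well.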
